A study of Homo sapiens with 9600 samples.

How the data were processed

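The series measured RNA in single cells of human pancreatic islets, the hormone-secreting cell clusters of the pancreas, from non-diabetic (ND) and type 2 diabetic (T2D) sources. The labels described 9600 single-cell libraries made on Fluidigm C1 chips, microfluidic devices with 800 chambers that capture 1 cell each, with polyadenylated RNA reverse-transcribed in the chamber and Nextera XT libraries made from the cDNA. Groups were taken from the source field, which gave 4 ND codes and 7 T2D codes. The title field of every library said non-diabetic, also for libraries whose source field said T2D, and the source field was followed. The first T2D code covered 2 chips, which were summed to 1 preparation, so that 12 chips made 11 preparations. The labels did not say that a code was a donor, and they gave no batch other than the chip. Each chip held 1 preparation, so chip and preparation cannot be separated, and the p-values of gene and share tests measure only spread between preparations.

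The deposited table held raw read counts per gene and chamber, with no normalization by the authors. Per the submitters' processing notes, reads were handled with Bowtie2 2.2.6 and SAMtools 1.2 on the human genome build hg19. The counting tool, the gene annotation and the reason why 7181 of the 9600 labelled chambers were in the table were not stated. No molecular identifiers were used, so counts include copies made by PCR. The table had 26471 NCBI gene numbers, of which 26324 matched a symbol in a current RefSeq table. Genes of the mitochondrial genome were missing, so the list of 13 such genes could not be tested, and the usual mitochondrial filter could not be applied. Overlapping genes each received the same reads: 412 genes fell into 176 groups with equal counts in every chamber, such as INS and the readthrough gene INS-IGF2. No gene positions are given, since the reference at hand is a later genome build than the one the authors used. Transcript lengths and gene spans came from that later build and served only to match or rank genes.

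Chambers with at least 500 genes and 5000 counts were kept (7140), and 147 called as doublets by Scrublet (scanpy 1.11.5), run per chip, were removed, which left 6993 cells. Counts were scaled to the median total, log-transformed, and centred within each chip. From the 2000 genes with the largest variance within chips, 30 principal components and 15 neighbours gave Leiden clusters at resolution 1 (leidenalg 0.10.2). Genes that repeated the counts of another gene, genes on the Y chromosome and XIST were left out of the clustering. A first clustering on genes scaled to unit variance split cells by genes that share reads; it was replaced after its clusters were seen and is kept as an alternative. A cluster took the class whose fixed marker list had at least 3 raised members and led its 10 genes of highest fold. This naming rule was written after the clusters were seen and before any T2D against ND test. The classes are called beta-like, alpha-like and so on, because they rest on RNA alone.

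Counts were summed per preparation over the cells of a class. A preparation entered with at least 20 cells, and a class was tested with at least 3 preparations per group. T2D and ND sums were compared with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test; R 4.3.3), with Benjamini-Hochberg adjustment over tested genes and a threshold of 0.05. All tests were two-sided. Levels are CPM of these sums, counts scaled to a common library size, given as mean and SD over preparations, and fold changes are edgeR's with their standard error (SE). Genes on the Y chromosome and XIST were never tested. PP-like cells formed no cluster at resolution 1 (at resolution 2 a cluster of 95 cells was PP-like), and ductal-like, mesenchymal-like and acinar-like cells were too few in at least 1 group for a gene test. Whether the T2D difference differed between beta-like and alpha-like cells was tested with edgeR as an interaction, with preparation as a block. Shares of cells per preparation were compared by an exact permutation test over all 330 splits of 4 against 7, adjusted over 6 classes. For the share of cells in a single preparation the 95% Wilson interval is given, which covers the error of counting cells only.

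Of 19 gene lists, 18 were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over lists within a class. Camera asks whether a list's genes differ from the other genes. With the preset correlation it takes the genes of a list as nearly independent, so its p-values do not measure spread between preparations alone. Camera with an estimated correlation, and fry, which asks whether the list's genes move on balance in 1 direction, were the alternatives. The lists, tests, filters and the rule for named genes were fixed before the data were examined. The rule names, per class, the islet hormones with BACH2 and AFF3, the genes past the threshold with the largest changes (with fewer than 10 such genes, the 5 smallest p in each direction among genes with at least 20 CPM in 1 group), and up to 4 members per list with the smallest p; TTR and BACH1 were fixed as well.

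Alternatives fixed in advance were DESeq2 1.42.0 on the same sums, no low-count filter, every chamber thinned to 5000 counts, doublets kept, chambers with 2 hormones removed, gene minimums of 1000 and 250 per chamber, the 2 chips of the first T2D code as separate samples, hormone genes left out before TMM, limma on mean log values of cells, Leiden resolutions of 0.5 and 2, no centring, and leaving out each preparation in turn. A chamber had 2 hormones when the second of INS, GCG, SST and PPY took over 10% of the counts of these 4 genes. Gene lists with thinned counts, without chambers of 2 hormones or without hormone genes, lists on the interaction, the first clustering and the alpha-like test within clusters 0 and 1 were added after the data had been seen.

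The tests were also run on simulated data in which 200 genes were changed 2-, 4- or 8-fold. The counts were drawn with edgeR's own dispersions and TMM library sizes, which may favour edgeR. For limma, separate normal values were drawn with the spread of its own residuals, so the tools cannot be ranked by these false calls. In beta-like cells edgeR recovered 2.99%, 52.2% and 93.9% of them with 4 false calls, and DESeq2 23.9%, 80.6% and 97.0% with 79 false calls. In alpha-like cells edgeR recovered 7.46%, 67.2% and 98.5% with 3 false calls, DESeq2 25.4%, 86.6% and 98.5% with 88, and limma made 8 false calls. In delta-like cells edgeR recovered 4.48%, 34.3% and 66.7% with 1 false call and DESeq2 made 130; for the interaction edgeR made 2 false calls and DESeq2 130. Camera found the shifted list with 0 false calls in each of the 3 classes under both correlations. The simulated genes were drawn independently, so this does not show how often camera calls lists whose genes move together. In the real data the estimated correlation was 0.195 for oxidative phosphorylation in alpha-like cells and 0.893 for acinar markers in beta-like cells. Other splits of the preparations were ranked by the number of genes with an unadjusted p under 0.05, a measure chosen after 0 genes had passed the threshold.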

Results

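Single-cell RNA of human islets was read in 4 ND and 7 T2D preparations to compare the cells of diabetic and non-diabetic islets. The title of the series concerns BACH2, a transcription repressor, in the failing beta cell. After filters, 2406 ND cells and 4587 T2D cells remained. Total counts per ND preparation were 297911221, 203842097, 217732978 and 218518187 for replicates 1 to 4. The T2D preparations had 543962366 (replicate 1, on 2 chips), 220024834, 178125487, 247833350, 193810239, 229408772 and 261966345 counts. Median counts per cell ranged from 299552 in ND replicate 2 to 423494 in T2D replicate 4.

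Beta-like cells, which express insulin (INS) and amylin (IAPP), made up 44.2% ± 3.44 of ND cells (SD, n = 4) and 26.3% ± 12.4 of T2D cells (n = 7). All 7 T2D preparations lay below the ND median. The exact permutation test gave p = 0.0182, and 0.109 after adjustment over 6 classes, so the difference did not pass. Ductal-like cells, with keratins and MMP7, made up 3.21% ± 1.57 of ND cells (n = 4) and 11.3% ± 9.95 of T2D cells (n = 7). All 7 T2D preparations lay above the ND median (exact p = 0.127, adjusted 0.255), and the difference of 8.04 points was 4.95 without T2D replicate 5. Alpha-like cells, which express glucagon (GCG), took 36.7% ± 4.5 in ND and 34.7% ± 13.2 in T2D (exact p = 0.827, adjusted 0.976). Delta-like cells, which express somatostatin (SST), took 5.13% ± 3.79 in ND and 9.63% ± 4.53 in T2D (exact p = 0.118, adjusted 0.255). The delta-like difference of 4.50 points ranged from 2.13 with the first clustering to 6.39 without ND replicate 4. Mesenchymal-like cells took 4.49% ± 2.02 and 3.8% ± 2.79 (exact p = 0.697, adjusted 0.976). Acinar-like cells took 1.19% ± 1.03 and 2.6% ± 6.18 (exact p = 0.976, adjusted 0.976). Without T2D replicate 5 the acinar difference of 1.41 points turned to -0.929 (exact p = 0.0429, adjusted 0.0952), and it turned to lower as well with doublets kept (-3.73), with 250 genes (-3.92) and at Leiden resolution 0.5 (-0.769). Clusters that matched no class held 5.15% ± 2.1 of ND and 11.8% ± 11.2 of T2D cells, and 7.77% of T2D cells without T2D replicate 5. T2D replicate 5 stood apart, with 4.77% beta-like cells (95% Wilson interval 3.25 to 6.95), 29.8% ductal-like cells (26 to 33.8), 16.6% acinar-like cells (13.7 to 20) and 36.1% unnamed cells (32.1 to 40.3). Its unnamed cells included a cluster of 86 with TTR, GCG, INS and SST among the leading genes. Its beta-like and alpha-like shares may thus be too low, which the intervals do not cover. Without T2D replicate 5 the difference in the beta-like share was -14.3 points. The chips of T2D replicate 1 gave 23.1% (19.8 to 26.7) and 29.6% (26.1 to 33.4) beta-like cells.

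**Figure D1:**
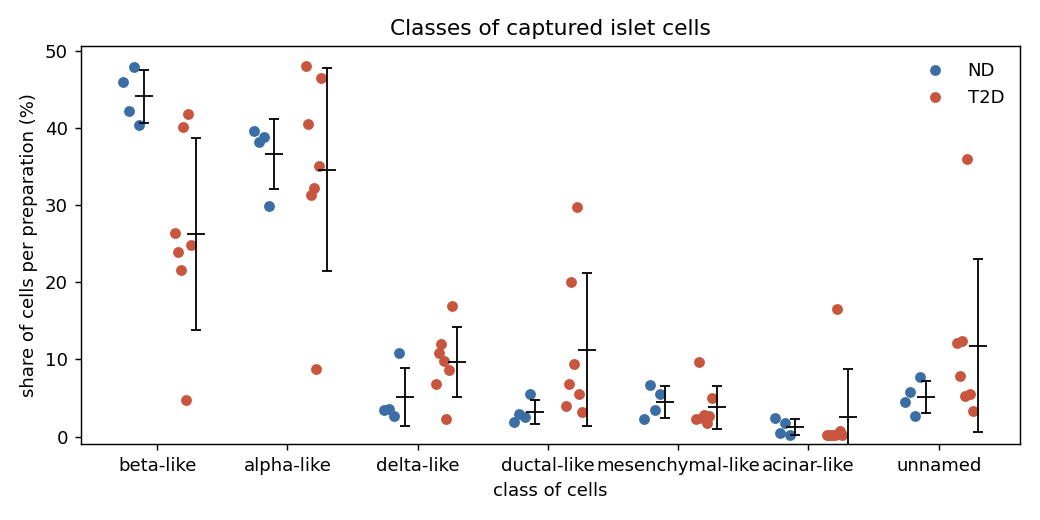
Share of cells (%) of each class per preparation, with ND in blue and T2D in red; each point is a preparation, and bars give the mean and SD. The 7 T2D preparations lie below the ND median for beta-like cells and above it for ductal-like cells, with neither difference past the adjusted threshold.

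ND and T2D beta-like cells lay largely in different clusters. Pooled over preparations, 44.2% and 23.1% of ND beta-like cells lay in clusters 7 and 11, which held 2.74% and 1.82% of T2D cells. Of T2D beta-like cells, 37.4% and 31.7% lay in clusters 3 and 6, which held 8.09% and 12.4% of ND cells. ND replicate 4 lay with the T2D cells: 140 of its 221 beta-like cells were in clusters 3 and 6, of 218 ND cells there, and 27 in clusters 7 and 11. The comparisons of beta-like cells were made over the whole class and not within clusters. In beta-like cells, INS (gene 3630) was measured at 129355 ± 61932 CPM in ND (SD, n = 4) and 61683 ± 16855 in T2D (n = 7). This was a log2 fold change of -1.07 ± 0.30 (SE), and all 7 T2D preparations lay below the ND median. IAPP (gene 3375) had 13364 ± 8671 and 6363 ± 5316 CPM, a log2 fold change of -1.07 ± 0.75. TTR, the transthyretin gene, had a log2 fold change of -1.18 ± 0.40. The edgeR adjusted p was 0.426 for INS, 0.659 for IAPP and 0.437 for TTR, so none of the 3 passed. Without ND replicate 1 the TTR fold change was -0.60. BACH2 (gene 60468) had 220 ± 64.0 CPM in ND and 192 ± 60.6 in T2D, a log2 fold change of -0.20 ± 0.28 with an adjusted p of 0.865 in edgeR. It was -0.03 without ND replicate 3, -0.37 without ND replicate 4, -0.09 without T2D replicate 3 and -0.31 without T2D replicate 5. Over all alternatives the fold change of BACH2 ranged from -0.66 to -0.03. Its relative BACH1 had a log2 fold change of 0.19 ± 0.26, and AFF3, a nuclear factor gene, of 0.25 ± 0.42. In leave-one-out fits BACH1 ranged from 0.11 (without T2D replicate 6) to 0.31 (without ND replicate 3) and AFF3 from 0.11 (without ND replicate 1) to 0.43 (without ND replicate 4). AFF3 turned to lower in T2D with thinned counts, at Leiden resolution 0.5 and without centring. The other hormone genes did not pass either, with log2 fold changes of 1.71 ± 0.80 for GCG, 0.52 ± 0.59 for SST and -0.13 ± 1.2 for PPY. Over the alternatives GCG ranged from 0.07 without centring to 2.69 at Leiden resolution 0.5, with 0.47 without chambers of 2 hormones. SST ranged from 0.23 without T2D replicate 3 to 2.48 at Leiden resolution 0.5, with 0.24 without ND replicate 2, 0.34 without T2D replicate 2 and 1.003 without ND replicate 4. PPY turned to higher without chambers of 2 hormones, at Leiden resolution 0.5 and with the first clustering. Chambers with 2 hormones made up 9.47% ± 5.0 of ND and 16.5% ± 6.42 of T2D beta-like cells.

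**Figure D2:**
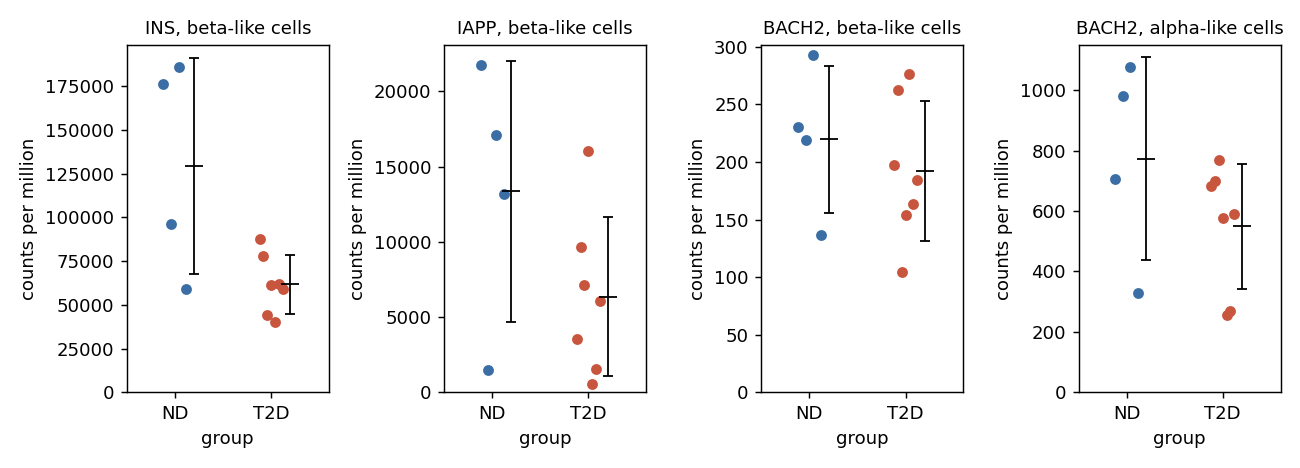
CPM of INS, IAPP and BACH2 in beta-like cells and of BACH2 in alpha-like cells, per preparation; points are preparations and bars give the mean and SD. INS lies below the ND median in all 7 T2D preparations, while the BACH2 levels of the groups overlap in both classes.

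Of 19451 genes tested in beta-like cells, edgeR called 0, with 1027 higher and 843 lower at an unadjusted p under 0.05 where 973 are expected by chance. DESeq2 called 348 (231 higher, 117 lower in T2D) and limma 0. The genes of smallest p on the higher side were above the ND median in all 7 T2D preparations, though none passed. SOX4 (gene 6659), a transcription factor of islet progenitors that was also among the 10 leading genes of the ductal-like cluster, had 21.4 ± 9.36 CPM in ND and 162 ± 106 in T2D, a log2 fold change of 2.92 ± 0.57. GALNT10 had 1.89 ± 0.36, MSMO1, an enzyme of cholesterol synthesis, 1.27 ± 0.25, BZW2 1.25 ± 0.23 and the readthrough gene C1QTNF3-AMACR 2.01 ± 0.39. On the lower side were LRRFIP2 (-1.25 ± 0.25), CRCP (-1.27 ± 0.27), ULK4 (-1.26 ± 0.27), CFAP43 (-1.98 ± 0.43) and ERLN (-1.83 ± 0.40), below the ND median in all 7 T2D preparations. The adjusted p of these 10 genes in edgeR lay between 0.284 and 0.310.

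Camera called 8 of 18 gene lists in beta-like cells, 7 higher and 1 lower in T2D, and fry called 0. These calls compare ND and T2D cells that lay largely in different clusters of the class. As 0 genes passed over all genes, members are also counted adjusted over the list alone. Cytokine and inflammation genes were higher as a group (23 of 25, median log2 fold change 2.77, adjusted p = 3.34e-07). The adjusted p was 0.216 with an estimated correlation, and 8 members passed adjusted over the list alone. It was the strongest list in beta-like cells, with a camera statistic of 5.63. In other splits of the preparations the strongest list of these cells had a statistic of 1.87 to 10.4, so chance stays open for this call. The acute-phase gene SERPINA3 had 2.96 ± 2.44 CPM in ND and 153 ± 217 in T2D, and the chemokine gene CXCL1 0.72 ± 0.27 and 25.7 ± 35.2 CPM. Ductal markers were higher as well (11 of 11, median 3.28, adjusted p = 4.10e-05). Their adjusted p was 0.216 with an estimated correlation, and 1 passed adjusted over the list alone. KRT19 had 2.54 ± 1.35 CPM in ND and 64.9 ± 137 in T2D (log2 fold change 4.67, and 2.42 without T2D replicate 5), and MMP7 0.08 ± 0.06 and 24.5 ± 35.3 CPM. The score of the inflammation list, the median over its genes of log2(CPM + 1) relative to the ND mean, was 2.50, 1.93 and 1.68 in T2D replicates 3, 5 and 6. It was between -0.11 and 0.41 in the other 4 T2D preparations. The score of the ductal list was 3.10 and 4.66 in T2D replicates 3 and 5 and at most 0.76 in the rest. The ductal call was lost with thinned counts (adjusted p = 0.0803, in a range of 3.49e-06 to 0.216 over all alternatives).

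Immediate early and dissociation stress genes were higher in T2D beta-like cells (22 of 31, median log2 fold change 0.77, camera adjusted p = 1.65e-06). With an estimated correlation it was 0.184, and 4 members passed adjusted over the list alone. KLF6 had a log2 fold change of 1.46 ± 0.32 and FOSL2 of 2.79 ± 0.51, both above the ND median in all 7 T2D preparations. Interferon and HLA class I genes, of which the HLA genes serve antigen presentation, were higher in 29 of 33 (median 0.86, adjusted p = 0.00165). The adjusted p was 0.216 with an estimated correlation, and 0 passed adjusted over the list alone. HLA-E had a log2 fold change of 1.45 ± 0.50 and HLA-B of 0.89 ± 0.32. Genes normally kept silent in mature beta cells or active in progenitors were higher in 15 of 23 (median 1.04, adjusted p = 0.0339). With an estimated correlation it was 0.216, and 1 gene, SOX4, passed adjusted over the list alone. In that list LDHA, a lactate dehydrogenase, had a log2 fold change of 2.91 ± 0.97 and HES1 of 2.50 ± 0.90, and without T2D replicate 5 these were 1.88 and 1.15. Its call was lost without T2D replicate 3 (adjusted p = 0.0533) or T2D replicate 5 (0.11), with thinned counts (0.0665) and without chambers of 2 hormones (0.0554). The share of ductal RNA in beta-like cells, estimated from ductal markers, was 4.15% in T2D replicate 3 and 23.7% in T2D replicate 5. Whether ductal RNA gave the rise of this list was not tested.

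Genes of the unfolded protein response, which serves protein folding in the endoplasmic reticulum, were the 1 list lower in T2D beta-like cells (20 of 27 lower, median log2 fold change -0.42, camera adjusted p = 0.0155). The adjusted p was 0.311 with an estimated correlation, and 1 member higher and 1 lower passed adjusted over the list alone. The chaperone genes SDF2L1 and HSP90B1 had log2 fold changes of -1.55 ± 0.37 and -1.07 ± 0.33, while ATF3, a stress-induced transcription factor gene, had 1.15 ± 0.31. This call was lost without ND replicate 3 (adjusted p = 0.169). Cholesterol synthesis genes were higher in 19 of 24 (median 0.34, adjusted p = 0.0339), with HMGCS1 at 0.84 ± 0.28. With an estimated correlation it was 0.700, and 1 passed adjusted over the list alone. BACH factors with antioxidant genes were higher in 19 of 30 (median 0.28, adjusted p = 0.0359), with SQSTM1 at 0.73 ± 0.21 and the antioxidant regulator NFE2L2 at 1.21 ± 0.41. Here the adjusted p was 0.216 with an estimated correlation, and 0 passed adjusted over the list alone. The cholesterol call was lost without ND replicate 1 (adjusted p = 0.0715) or 2 (0.0757), without T2D replicate 1 (0.0794), 4 (0.0702) or 7 (0.126), and without chambers of 2 hormones (0.054). BACH2 and BACH1 themselves had log2 fold changes of -0.20 and 0.19. The call of the BACH and antioxidant list was lost without ND replicate 1 (0.0579), 2 (0.0559) or 4 (0.0968), without T2D replicate 1 (0.0768), 4 (0.0702) or 5 (0.11), and with thinned counts (0.238).

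The beta cell identity list did not differ from other genes (20 of 30 higher, median log2 fold change 0.44, camera adjusted p = 0.535, 0 adjusted over the list alone). Its members went both ways. The ectonucleotidase gene ENTPD3 had a log2 fold change of -1.41 ± 0.54, PFKFB2 of -0.98 ± 0.33 and ISL1, a transcription factor of endocrine cells, of 1.37 ± 0.47. Insulin secretion machinery (18 of 31 higher, adjusted p = 0.726), alpha cell identity (15 of 21, 0.792) and oxidative phosphorylation (23 of 74, 0.535) were not called either. The same held for glycolysis (17 of 27 higher, with VEGFA at 1.40 ± 0.29), ribosomal proteins (17 of 77), acinar markers (16 of 16), mesenchymal markers (9 of 13) and delta and PP markers (13 of 17), each with an adjusted p of 0.0502. Adjusted over the list alone, 1 glycolysis gene passed and 0 of the other lists in this paragraph. Each of these 5 lists passed without at least 1 single preparation. Acinar markers were not called without T2D replicate 5 (adjusted p = 0.512), where their direction turned to lower. Oxidative phosphorylation was called lower without ND replicate 2 (0.0035). Endothelial and immune markers were higher in 5 of 10 (adjusted p = 0.938), with a median log2 fold change of -0.06 and a mean of 0.24.

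In alpha-like cells, genes of oxidative phosphorylation, the energy-producing chain of mitochondria, were higher as a group in T2D. All 74 measured members had a positive log2 fold change, with a median of 0.80, and 53 had an unadjusted p under 0.05. Camera gave an adjusted p of 6.40e-23 and fry 0.000908, while the adjusted p was 0.0680 with an estimated correlation. Over all genes 0 members passed, and 48 passed adjusted over the list alone. ATP5MC1 (gene 516), a subunit of ATP synthase, had 45.4 ± 23.5 CPM in ND (SD, n = 4) and 152 ± 41.5 in T2D (n = 7), a log2 fold change of 1.75 ± 0.33. ATP5PB (1.16 ± 0.22), NDUFS3 (1.35 ± 0.29) and NDUFC1 (0.98 ± 0.20) were likewise above the ND median in all 7 T2D preparations. The list score was -0.29 to 0.39 in the 4 ND preparations, highest in ND replicate 4, and at least 0.64 in each of the 7 T2D preparations. ND and T2D alpha-like cells lay largely in different clusters. Pooled over preparations, 47.9% and 25.2% of ND cells lay in clusters 5 and 12, and 42.5% and 40.4% of T2D cells in clusters 0 and 1. Within clusters 0 and 1, with 3 ND and 7 T2D preparations, the median of the list was 0.35 (camera adjusted p = 0.000347, and 0.580 with an estimated correlation).

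Glycolysis genes were higher in T2D alpha-like cells in 23 of 27 members (median log2 fold change 0.45, camera adjusted p = 0.000238). Of the 9 lists called higher by camera in these cells, it was the 1 whose call was kept with an estimated correlation (adjusted p = 0.0199), and fry called it too (0.000186). Adjusted over the list alone, 7 members passed. PGK1 had 66.9 ± 44.6 CPM in ND and 198 ± 26.6 in T2D (log2 fold change 1.57 ± 0.33), and TPI1 177 ± 16.5 and 420 ± 142 CPM (1.25 ± 0.26). Immediate early genes were higher in 27 of 31 (median 0.67, adjusted p = 0.000970). The adjusted p was 0.146 with an estimated correlation and 0.0171 by fry, and 2 members higher and 1 lower passed adjusted over the list alone. KLF6 had 333 ± 74.3 CPM in ND and 692 ± 197 in T2D. GADD45B, a stress gene of the same list, had a log2 fold change of -1.96 ± 0.42. The immediate early call was lost with thinned counts (adjusted p = 0.0762).

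Interferon and HLA class I genes were higher in 29 of 33 members in T2D alpha-like cells (median log2 fold change 1.12, camera adjusted p = 0.000238). With an estimated correlation it was 0.502, and 5 members higher and 1 lower passed adjusted over the list alone. PSMB10, of the immunoproteasome, had a log2 fold change of 3.25 ± 0.84 and TAPBP, of peptide loading, of 1.19 ± 0.36. Cytokine and inflammation genes were higher in 23 of 27 (median 2.77, adjusted p = 0.00239). Their adjusted p was 0.53 with an estimated correlation, and 0 passed adjusted over the list alone. CXCL1 had 3.15 ± 1.57 CPM in ND and 51.6 ± 58.0 in T2D. The inflammation score was 2.11, 2.04 and 2.64 in T2D replicates 3, 5 and 6 and between -0.24 and 0.15 in the other 4. The inflammation call was lost with thinned counts (adjusted p = 0.0978). Ductal markers were higher in 10 of 12 (median 2.45, adjusted p = 0.0479), with KRT19 at 5.99 ± 1.89 CPM in ND and 103 ± 229 in T2D (log2 fold change 4.09, and 1.43 without T2D replicate 5). Their adjusted p was 0.53 with an estimated correlation, and 0 passed adjusted over the list alone. The ductal call was lost without ND replicate 3 (adjusted p = 0.0759) or 4 (0.163), without T2D replicate 3 (0.136) or 5 (0.166), with thinned counts (0.471) and without chambers of 2 hormones (0.0666).

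Cholesterol synthesis genes were higher in 20 of 24 in T2D alpha-like cells (median log2 fold change 0.63, camera adjusted p = 0.00178), with FDFT1, a squalene synthase gene, at 1.09 ± 0.27. The adjusted p was 0.53 with an estimated correlation, and 1 passed adjusted over the list alone. Secretion machinery genes were higher in 23 of 31 (median 0.40, adjusted p = 0.0195), with RPH3AL at 1.45 ± 0.46 and VGF, a granule protein gene, at 1.07 ± 0.37. Here too the adjusted p was 0.53 with an estimated correlation, and 0 passed adjusted over the list alone. The secretion call was lost without ND replicate 2 (adjusted p = 0.0996) or T2D replicate 7 (0.0723) and with thinned counts (0.175). BACH factors with antioxidant genes were higher in 19 of 30 (median 0.49, adjusted p = 0.0479), with NFE2L1 at 0.97 ± 0.30 and GCLM, of glutathione synthesis, at -1.02 ± 0.30. Their adjusted p was 0.53 with an estimated correlation, and 0 passed adjusted over the list alone. BACH2 and BACH1 themselves had log2 fold changes of -0.49 and -0.12 in these cells. The call of the BACH and antioxidant list was lost without ND replicate 1 (adjusted p = 0.112) or 4 (0.154), without T2D replicate 4 (0.0713) or 5 (0.166), with thinned counts (0.471) and without chambers of 2 hormones (0.0666).

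Not called in alpha-like cells were alpha cell identity (13 of 23 higher, camera adjusted p = 0.549), beta cell identity (20 of 30, 0.548), disallowed genes (20 of 25, 0.0970) and the unfolded protein response (10 of 27, 0.548). Ribosomal proteins (43 of 77, 0.315), delta and PP markers (14 of 17, 0.126) and endothelial and immune markers (4 of 13, 0.366) were not called either. Disallowed genes passed without T2D replicate 1 (0.0321) or 4 (0.038), delta and PP markers without T2D replicate 1 (0.0321) and ribosomal proteins without ND replicate 3 (0.00578). Acinar markers were not called (0.25), and here the measures differed in sign: camera put the list lower, although 16 of 16 members had a positive fold change with a median of 2.59. The score of that list was 5.67 in T2D replicate 5 and between -4.29 and 0.06 in the other 6. Camera called acinar markers lower without T2D replicate 5 (adjusted p = 6.43e-05) and with thinned counts (0.0407). Mesenchymal markers (adjusted p = 0.245) had a camera direction of lower with a median of 0.02 and a mean of -0.39. Adjusted over the list alone, 1 ribosomal protein gene and 2 mesenchymal markers passed, and 0 of the other lists in this paragraph.

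GCG had 28159 ± 1400 CPM in ND alpha-like cells and 34829 ± 16915 in T2D, a log2 fold change of 0.31 ± 0.41 with an edgeR adjusted p of 0.700, and 0.18 without T2D replicate 1 and 0.49 without T2D replicate 5. TTR had 100485 ± 47819 and 61178 ± 9006 CPM (-0.72 ± 0.25, adjusted p = 0.155 in edgeR, and -0.40 without ND replicate 1). BACH2 had 773 ± 335 CPM in ND and 549 ± 207 in T2D, a log2 fold change of -0.49 ± 0.37 (adjusted p = 0.461), and all 7 T2D preparations lay below the ND median. It was -0.28 without ND replicate 3 and -0.75 without ND replicate 4. BACH1 had a log2 fold change of -0.12 ± 0.31, in a range of -0.40 (without T2D replicate 5) to -0.03 (without T2D replicate 3) over leave-one-out fits. AFF3 had 33.1 ± 12.1 and 14.9 ± 4.45 CPM (-1.15 ± 0.33, adjusted p = 0.108), also below the ND median in all 7. INS (-0.80 ± 0.40), IAPP (-0.33 ± 0.91), SST (0.03 ± 0.58) and PPY (-1.40 ± 0.95) did not pass, and the direction of SST and IAPP turned under some alternatives. Over all alternatives INS ranged from -1.78 to -0.63, IAPP from -1.45 to 0.55 and SST from -0.67 to 1.58. PPY was at -0.24 without ND replicate 1. AFF3 passed without ND replicate 4 and with DESeq2. Chambers with 2 hormones made up 31.6% ± 7.6 of ND and 33.8% ± 7.02 of T2D alpha-like cells.

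Of 19954 genes tested in alpha-like cells, edgeR called 0, with 2070 higher and 1890 lower at an unadjusted p under 0.05 where 998 are expected by chance. DESeq2 called 2122 (1285 higher, 837 lower) and limma 746 (354 higher, 392 lower). ND replicate 4 had 126 of its 164 alpha-like cells in clusters 0 and 1, where most T2D cells lay. Without it edgeR called 676 genes (382 higher, 294 lower), and with the chips of T2D replicate 1 as separate samples it called 237. The fit with separate chips counts 1 preparation as 2 samples, which are not independent. In the main edgeR fit the 10 genes with the smallest p all had an adjusted p of 0.0539. TMEM45B (gene 120224), which encodes a membrane protein, had 6.98 ± 2.23 CPM in ND and 60.9 ± 22.1 in T2D, a log2 fold change of 3.13 ± 0.41. ERLIN2 (3.39 ± 0.52), TMEM208 (1.5 ± 0.25), the co-chaperone gene PTGES3 (1.16 ± 0.19) and PARK7, a redox-sensitive protein gene (1.06 ± 0.18), were also above the ND median in all 7 T2D preparations. TPMT, a thiopurine methyltransferase gene, had 69.6 ± 27 CPM in ND and 19 ± 4.74 in T2D (-1.88 ± 0.30). NUP210L (-1.84 ± 0.28), CDKL4 (-3.04 ± 0.50), BALR6 (-3.13 ± 0.53) and the RNA-binding protein gene CELF5 (-2.24 ± 0.38) were, like TPMT, below the ND median in all 7.

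**Figure D3:**
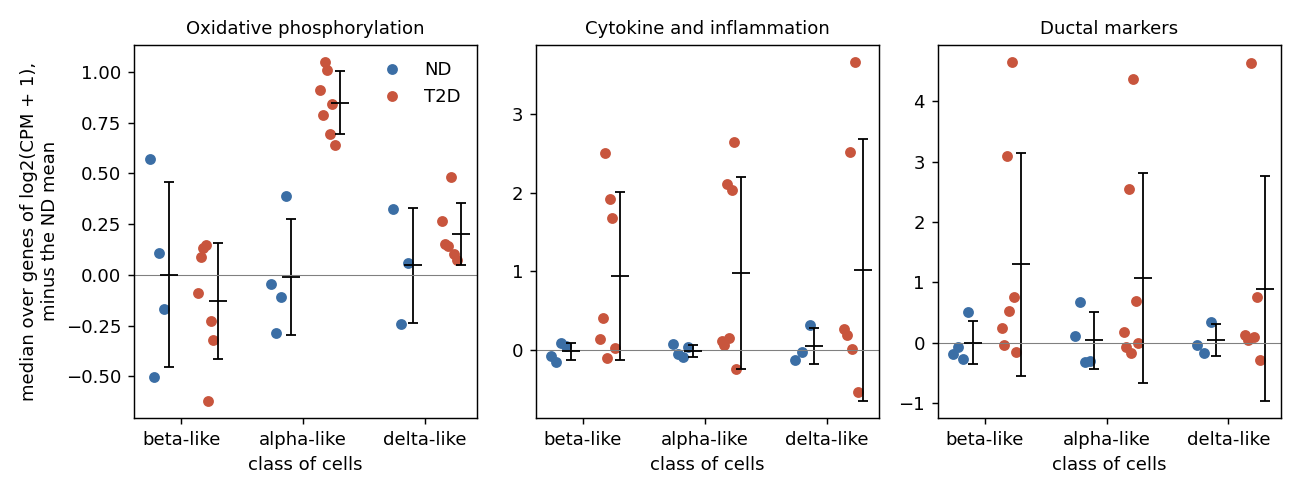
List scores per preparation (median over the genes of a list of log2(CPM + 1), minus the ND mean) for oxidative phosphorylation, inflammation and ductal markers in beta-like, alpha-like and delta-like cells; points are preparations and bars give the mean and SD. Oxidative phosphorylation lies at 0.64 or more in T2D alpha-like cells against -0.29 to 0.39 in ND, while the inflammation and ductal scores are high in a few T2D preparations.

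In delta-like cells, compared in 3 ND and 6 T2D preparations, TTR had 10091 ± 3306 CPM in ND and 3931 ± 788 in T2D, a log2 fold change of -1.36 ± 0.24. The ND sums held 25, 22 and 59 cells. TTR is a marker of alpha cells, with 100485 CPM in ND alpha-like cells, and was also lower in T2D beta-like and alpha-like cells. INS had 50023 CPM in ND and 21107 in T2D delta-like cells. Whether RNA of other islet cells gave the TTR difference was not tested. SST itself had 104352 ± 30491 and 106854 ± 27407 CPM (0.03 ± 0.26, adjusted p = 0.976 in edgeR), and BACH2 146 ± 69.7 and 105 ± 25.7 CPM (-0.47 ± 0.35, adjusted p = 0.650). The BACH2 fold change was -0.0027 without ND replicate 1 and -0.74 without ND replicate 4. INS (-1.24 ± 0.42), GCG (0.65 ± 0.66), IAPP (0.46 ± 0.81), PPY (-0.85 ± 1.10), BACH1 (-0.20 ± 0.50) and AFF3 (0.01 ± 0.69) did not pass. INS was at -0.75 without ND replicate 1, and GCG at 1.08 without ND replicate 2 and 0.18 without T2D replicate 7. Chambers with 2 hormones made up 61.5% ± 12.9 of ND (n = 4) and 44.5% ± 14.8 of T2D (n = 7) delta-like cells, and no fit of delta-like cells was made without them. Of 17165 genes tested, edgeR called 0, with 976 higher and 861 lower at an unadjusted p under 0.05 where 858 are expected. DESeq2 called 476 (365 higher, 111 lower). The genes with the smallest p, TTR among them, had an edgeR adjusted p of 0.360. LGMN, a lysosomal protease gene, had 20.8 ± 1.67 CPM in ND and 75.9 ± 11.9 in T2D (1.87 ± 0.33), ECHDC2 had 2.35 ± 0.47 and LOC100506076 had 2.09 ± 0.40. DTX3L had 0.24 ± 0.26 CPM in ND and 21 ± 8.71 in T2D, and KNOP1 0.29 ± 0.16 and 20.3 ± 14.9 CPM. On the lower side AUH had -1.80 ± 0.39 and PDE9A, a cyclic GMP phosphodiesterase gene, -2.52 ± 0.57. TTC29 had 22.5 ± 27.1 CPM in ND and 0.55 ± 0.17 in T2D, and CPO 25.1 ± 35.6 and 0.50 ± 0.47 (log2 fold change -5.61, and -3.20 without ND replicate 2).

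Camera called 4 lists in delta-like cells, and neither fry nor camera with an estimated correlation called any. Cholesterol synthesis genes were higher in 20 of 23 (median log2 fold change 0.80, adjusted p = 0.000190), with HMGCS1 at 1.33 ± 0.38 and MSMO1 at 1.35 ± 0.42. Interferon and HLA class I genes were higher in 25 of 31 (median 0.88, adjusted p = 0.0126). IFITM3, an antiviral membrane protein gene, had 1.06 ± 0.28 CPM in ND and 29.7 ± 38.9 in T2D, and was also among the 10 leading genes of the mesenchymal-like cluster. Delta and PP markers were higher in 13 of 16 (median 0.56, adjusted p = 0.0233), led by PRG4 with 58.8 ± 47.5 and 1002 ± 725 CPM and THSD7A (1.29 ± 0.29). The adjusted p of these 3 lists was 0.503 with an estimated correlation. Acinar markers were lower in 12 of 16 (median -1.24, adjusted p = 0.0153, and 0.653 with an estimated correlation), with CEL at 4.59 ± 6.80 and 0.25 ± 0.21 CPM (log2 fold change -4.20, and -1.44 without ND replicate 1). Over all genes 0 members passed; adjusted over the list alone, 3 delta and PP markers and 1 acinar marker passed, and 0 genes of the other called lists. The interferon call was lost without ND replicate 4 (0.108) or T2D replicate 6 (0.0587), the marker call without ND replicate 4 (0.108) or T2D replicate 7 (0.063). The acinar call was lost without ND replicate 1 (0.245) or 4 (0.12) and without T2D replicate 6 (0.0587) or 7 (0.0607).

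The other 14 lists were not called in delta-like cells. Disallowed genes (19 of 22 higher, camera adjusted p = 0.0657), the unfolded protein response (7 of 27, 0.0636), immediate early genes (22 of 30, 0.0709) and ribosomal proteins (19 of 77, 0.0546) each passed without at least 1 single preparation. So did oxidative phosphorylation (47 of 74, 0.208), beta cell identity (18 of 30, 0.187) and mesenchymal markers (10 of 12, 0.109). Glycolysis (17 of 26, 0.258), inflammation (15 of 20, 0.187), alpha cell identity (13 of 21, 0.537), secretion machinery (19 of 31, 0.803), BACH factors (16 of 30, 0.49) and ductal markers (7 of 9, 0.303) did not. Endothelial and immune markers (3 of 5, 0.777) were put lower by camera with a median of 0.02. Adjusted over the list alone, 1 alpha cell identity gene passed and 0 genes of the other 13 lists.

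Whether the T2D difference itself differed between beta-like and alpha-like cells was tested on 21674 genes. EdgeR called 0, with 722 higher and 1554 lower in beta-like relative to alpha-like cells at an unadjusted p under 0.05 where 1084 are expected, and DESeq2 called 877 (203 and 674). The genes with the smallest p included 2 of respiratory complex I, NDUFA13 (-1.38 ± 0.24) and NDUFB2 (-1.46 ± 0.26), with ERLIN2 (-3.32 ± 0.49), TMEM208 (-1.97 ± 0.31) and COMMD3 (-2.09 ± 0.36). NDUFB2 had 780 CPM in beta-like and 258 in alpha-like cells of ND preparations, and 734 and 649 CPM in T2D. On the other side were ZSWIM5 (1.33 ± 0.25), the calcium channel gene CACNA2D1 (1.67 ± 0.34), the kinase gene PRKCE (1.37 ± 0.29), GALNT10 (1.45 ± 0.31) and ADAMTSL4-AS1 (2.2 ± 0.47). Their edgeR adjusted p lay between 0.141 and 0.219, and none passed. Without ND replicate 4 edgeR called 138 genes (16 and 122).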

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

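The tests of the alpha-like pattern by splits of the preparations, by depth and by chip, and the test of unspliced RNA, were chosen after the results were seen. Those by transcript length, by cluster, by ductal RNA and by genomic DNA were chosen before theirs. A preparation far from the rest of its group was found in 13 of 78 groups tested, and chance gives about 1 in 20, here 3.9. Shares far from the group were 29.98% alpha-like and 10.79% delta-like cells in ND replicate 4 and 9.66% mesenchymal-like cells in T2D replicate 2 (95% Wilson intervals 26.3 to 34.0, 8.45 to 13.7 and 7.67 to 12.1). T2D replicate 5 had 8.78% alpha-like, 16.6% acinar-like and 36.1% unnamed cells (6.65 to 11.5, 13.7 to 20 and 32.1 to 40.3). TTR in beta-like cells was high in ND replicate 1 (15100 CPM) and low in T2D replicate 5 (926 CPM). T2D replicate 4 was high in IAPP and PPY of alpha-like cells (2091 and 6662 CPM) and in IAPP of delta-like cells (5679 CPM). BACH1 was high in alpha-like cells of T2D replicate 5 (136 CPM), and the ductal score was high in delta-like cells of T2D replicate 3 (4.64).

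For 6 gene lists the T2D difference of beta-like cells differed from that of alpha-like cells by camera, and for none of the 6 with an estimated correlation. Oxidative phosphorylation was lower in beta-like relative to alpha-like cells in 73 of 74 genes (median log2 difference -1.02, adjusted p = 5.51e-28, and 0.274 with an estimated correlation). Secretion machinery was lower in 26 of 31 (-0.38, 0.0107, and 0.497), glycolysis in 19 of 27 (-0.49, 0.0107, and 0.274) and ribosomal proteins in 68 of 77 (-0.19, 0.0107, and 0.720). Acinar markers were lower in 0 of 16 (2.27, 2.77e-07, and 0.497) and mesenchymal markers in 3 of 13 (1.14, 0.0279, and 0.643).

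The higher oxidative phosphorylation genes of T2D alpha-like cells were weighed against chance, depth, transcript length, chip and cluster. The list was picked as the strongest. It was therefore set against the strongest of the 18 lists in beta-like or alpha-like cells in 100 splits of the preparations. With the real split included, 2 of 100 had as large a camera statistic (10.1, highest other 10.4). Chance is thus argued against but not excluded, since another split gave a larger statistic. Depth as the whole cause was argued against by chambers thinned to 5000 counts (median log2 fold change 0.748, camera adjusted p 1.28e-14, and 0.287 with an estimated correlation). Short transcripts as the whole cause were argued against by 10000 random sets matched on expression and length. Of these, 0 reached the list's median of 0.80 (0.009999%, the smallest share they can give). The median of the matched sets was 0.32, so that length and expression stay open for part of the rise. The sets were drawn gene by gene, while the genes of the list move together (estimated correlation 0.195). The share of sets takes no account of that and does not measure spread between preparations. An equal shift of the ND chips in every cell is argued against as the whole cause, since the list score was higher by 0.86 in T2D alpha-like cells and had a difference of -0.13 in beta-like cells (Welch 95% interval -0.80 to 0.54; exact permutation p of the difference between classes 0.00303). Still open are the cells compared, since within clusters 0 and 1 the median was 0.348 (quartiles 0.10 to 0.52, camera adjusted p 0.000347, and 0.580 with an estimated correlation, 3 ND preparations), and, as untested, a T2D difference of alpha cells or a chip difference in these cells alone, because each chip held 1 preparation.

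The higher inflammation genes of T2D beta-like cells were weighed against RNA from ductal-like cells, and the median ratio of their excess to what the share of ductal markers gives was 2.10 over the 5 T2D preparations with a ratio. It was over 2 in T2D replicates 1, 3 and 6 (30.6, 2.10 and 74.2) and within 2 in T2D replicates 4 and 5 (0.555 and 0.524), and T2D replicate 2 had an excess of 276 CPM with no ductal share above that of ND, so no ratio. T2D replicate 7 was left out because its 18 ductal-like cells were fewer than 20. Ductal RNA gives 1.1 of an excess of 136 CPM in T2D replicate 1 and 12.1 of 1210 CPM in T2D replicate 6. With the excess of T2D replicate 2, this argues against ductal RNA as the main source of the excess in T2D replicates 1, 2 and 6. The list score was high only in T2D replicates 3, 5 and 6, though, so T2D replicates 1 and 2 hold little of the rise. Their ductal shares of 0.0077% and -0.13% were also too small for a stable ratio. Where the score was high, only T2D replicate 6 argues clearly against ductal RNA, and T2D replicate 3 lay close to the limit of 2. In T2D replicate 5, at a share of 23.7%, it could account for all. For the 6 preparations as a group, ductal RNA and inflammation of the cells cannot be told apart, because T2D replicates 4 and 5 lie on the other side. A T2D difference of beta cells stays open as untested.

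A signal was also found in 91 unnamed chambers, led by the very long genes CNTNAP2, PTPRD and EYS, with a median of 376412 counts against 363325 in other chambers. Olfactory receptor genes, 376 genes that islet cells hardly use, took 30.7 times the share of counts they took in other chambers (16.5 to 73.4 over 7 preparations, 5.82 to 12.2 CPM in total in the others), which fits reads from genomic DNA. The same ratio argues against unspliced RNA of genes that the other cells use as the whole cause, since olfactory receptor genes are not among these. No biological explanation was tested.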

How the results depend on the processing

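The 4 gene tests called 0 genes with edgeR, and the counts that moved were these. In beta-like cells DESeq2 called 348, the fit without chambers of 2 hormones 2, and leave-one-out fits 0 to 1. In alpha-like cells DESeq2 called 2122, limma 746, the 2 chips of T2D replicate 1 as separate samples 237, thinned counts 106, no chambers of 2 hormones 16, no centring 3, Leiden resolution 2 gave 1, and leave-one-out fits 0 to 676. In delta-like cells DESeq2 called 476 and thinned counts 2. The test between classes gave 877 with DESeq2, 26 with thinned counts and 0 to 138 in leave-one-out fits. On simulated data DESeq2 made 79 to 130 false calls, limma 8 in alpha-like cells and edgeR 1 to 4. These counts do not rank the tools, since the simulation used edgeR's dispersions and limma had a simulation of its own. Of camera's 8, 9 and 4 lists in beta-like, alpha-like and delta-like cells, an estimated correlation left 0, 1 and 0 and fry 0, 3 and 0. Thinned counts gave 5 in alpha-like cells, 4 of the 9 and acinar markers. Leave-one-out fits gave 6 to 12, 7 to 11 and 2 to 8. The cause of these moves was not tested. Among shares, beta-like cells kept a lower T2D share in 19 alternatives (-24.8 to -10.9 points, smallest adjusted p 0.0727). The exact permutation test gave p = 0.130 (adjusted 0.609) without centring and 0.0606 (adjusted 0.333) with the first clustering. The difference for alpha-like cells turned to 4.39 points with doublets kept, 4.47 with 250 genes, 3.37 at Leiden resolution 0.5 and 12.6 without centring (leave-one-out -4.26 to 2.29). That for mesenchymal-like cells turned to 0.221 without centring (-1.66 to 0.0709). That for acinar-like cells turned to -3.73 with doublets kept, -3.92 with 250 genes and -0.769 at Leiden resolution 0.5 (-0.929 to 1.81). Log2 fold changes of genes that had not passed turned sign as well. PPY in beta-like cells was 2.03 without chambers of 2 hormones, 1.79 at Leiden resolution 0.5 and 0.0482 with the first clustering (leave-one-out -0.54 to 0.44). AFF3 in beta-like cells was -0.37 with thinned counts, -0.43 at Leiden resolution 0.5 and -0.20 without centring. IAPP in alpha-like cells was 0.11 with the first clustering (-0.93 to 0.55). SST in alpha-like cells was -0.21 with thinned counts, -0.19 with doublets kept, -0.0700 with the 2 chips apart, -0.19 with 1000 genes, -0.000363 with 250 genes, -0.10 at Leiden resolution 2 and -0.67 with the first clustering (-0.29 to 0.62). AFF3 in delta-like cells was -0.0198 with DESeq2 and -0.0909 with doublets kept (-0.22 to 0.18). In leave-one-out fits of delta-like cells IAPP ranged from -0.0822 to 0.86, SST from -0.17 to 0.25, PPY from -1.43 to 0.0426 and BACH1 from -0.65 to 0.46. Lists not called also turned direction. In beta-like cells alpha cell identity (adjusted p 0.937 by fry, 0.167 without chambers of 2 hormones), secretion machinery (0.937 by fry, 0.868 thinned) and endothelial markers (0.955 without chambers of 2 hormones) did so. In alpha-like cells beta cell identity (0.862 without chambers of 2 hormones) and, with thinned counts, alpha cell identity (0.751), ribosomal proteins (0.273) and delta and PP markers (0.751) did. Leave-one-out fits turned these lists, given with the range of adjusted p: in beta-like cells beta cell identity (0.11 to 0.921), alpha cell identity (0.294 to 0.968), secretion machinery (0.180 to 0.921), oxidative phosphorylation (0.00350 to 0.992), ribosomal proteins (0.00124 to 0.939), acinar markers (0.00516 to 0.512) and endothelial markers (0.368 to 0.981). In alpha-like cells they were alpha cell identity (0.181 to 0.900), the unfolded protein response (0.0747 to 0.890) and ribosomal proteins (0.00578 to 0.900), and in delta-like cells alpha cell identity (0.232 to 0.859), secretion machinery (0.510 to 0.963), ductal markers (0.152 to 0.987) and endothelial markers (0.652 to 0.985). The alternatives planned for genes of PP-like, acinar-like, ductal-like and mesenchymal-like cells were not run, since those classes could not be tested, and 26 alternatives gave no value. Depth limits which genes can be tested: with chambers thinned to 5000 counts these were 10462 instead of 19451 in beta-like cells and 10633 instead of 19954 in alpha-like cells. No paired analysis was possible because the ND and T2D codes name different preparations.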

Other observations

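The test of BACH2 between classes and all splits of the preparations were chosen after the results had been seen. BACH2 was higher in alpha-like than in beta-like cells in 10 of 11 preparations, with a mean of 631 ± 268 CPM against 202 ± 60.3 (SD, n = 11). The mean log2 difference within preparations was 1.56 ± 0.77 (SD), with an exact sign-flip p of 0.00195. AFF3 was also higher in alpha-like cells in 10 of 11 preparations (1.24 ± 1.02, exact p = 0.00293), and BACH1 in 5 of 11 (0.00 ± 0.74, exact p = 0.996). The difference in BACH2 held for the mean over preparations, and 1 of the 11 did not show it.

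Unnamed chambers fell into 3 clusters. The first held 478 chambers of low depth, with a median of 82466 counts and PPY, REG1A, PRSS1, GCG and SST among its leading genes, and took 4.17% ± 1.87 of ND cells (n = 4) and 7.86% ± 5.36 of T2D cells (n = 7), or 6.14% without T2D replicate 5. The next held the 91 chambers led by long genes, 0.987% ± 1.33 of ND and 1.61% ± 1.61 of T2D cells, where single preparations moved the difference from 0.0524 points (without T2D replicate 3) to 1.26 (without ND replicate 2). The last held 86 chambers, all of T2D replicate 5, with TTR, GCG, INS and SST among its leading genes.

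The number of genes at an unadjusted p under 0.05 was compared with other splits of the preparations into groups of the same sizes, and the numbers of splits as large include the real split. Few splits gave as many genes in alpha-like cells (3960 genes, highest other 4077, 2 of 100 splits as large) or delta-like cells (1837, highest other 2033, 3 of 84). In the test between classes only the real split did (2276, highest other 1746, 1 of 40). Chance is argued against there but not excluded. In alpha-like and delta-like cells another split gave more genes, and the comparisons were not adjusted for one another. For beta-like cells chance stayed open (1870, highest other 3886, 10 of 100). The highest split in beta-like and alpha-like cells set T2D replicates 3, 5, 6 and 7 against the rest and called 307 and 144 genes with edgeR, more than the real split did. So many calls point to a structure of the samples, which was not tested. For the number of gene lists called by camera, chance stayed open in beta-like cells (8 lists, highest other 12, 31 of 100 splits), alpha-like cells (9, highest other 13, 28 of 100) and delta-like cells (4, highest other 12, 32 of 84).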
